A study of Mus musculus with 12 samples.

How the data were processed

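The series measured RNA in cells with high Lgr5-eGFP signal sorted from the small intestine of C57BL/6J mice. Lgr5 marks the dividing stem cells at the base of the intestinal crypts, and the eGFP reporter makes these cells visible to a cell sorter. The labels give the cells as an Lgr5-eGFP-creER knock-in while the growth notes call the mice wild-type, which leaves the genotype unclear, and a knock-in can alter the transcripts of the allele that carries it, so Lgr5 levels may not be those of wild-type cells. Per the labels' protocols, crypts were released with EDTA, dissociated enzymatically at 37 °C and sorted by fluorescence, total RNA was depleted of ribosomal RNA with the Ribo-Zero Gold kit, and libraries were made with the TruSeq RNA kit v2, which does not mark strand. The 12 libraries form 4 groups of 3 by sex and age, with young animals of 2 months and old animals of 18 to 26 months. The labels number the replicates but do not say that each came from a separate animal, so p-values measure the spread between these libraries, part of which could be technical.

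The deposited values are whole-number read counts per gene, 1 table per library, which the authors made from their reads. The submitters' processing notes name FastQC 0.11.5, TopHat2 2.1.0, Bowtie, HTSeq 0.11.2 and the mouse genome build mm9. The annotation, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Each table held 35002 rows, of which 35001 named a gene and 29042 had at least 1 count in some library. The row that named no gene was left out of library sizes and tests, and held 0.00122% to 0.00429% of a library's counts. Gene symbols were matched to the GENCODE vM1 annotation of NCBIM37, the assembly that mm9 is made from, and 33638 symbols matched, 342 of them to several loci. The other 1363 kept their deposited name without a position. Coordinates are 1-based positions of whole gene loci in that annotation, and counts cover all exons of a gene. Reads of near-identical genes (the defensin family, Hspa1a and Hspa1b, ribosomal protein genes and their pseudogenes) may have been dropped or split in counting, and reads of overlapping or antisense genes cannot be told apart without strand, so single values of such genes are uncertain.

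Total counts in named genes ran from 7634936 to 33350636 per library. At 3 counts, the floor used here for a gene with no counts, this corresponds to 0.0900 CPM in the deepest and 0.393 CPM in the shallowest library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed by far more than counting noise, with a chi-square of 13.2 to 110 per degree of freedom between pairs, so no library was treated as a duplicate.

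Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter by group, a robust quasi-likelihood fit and quasi-likelihood tests on a model of the 4 group means over all 12 libraries. The filter left 14969 genes, the residual degrees of freedom were 8 and the biological coefficient of variation was 26.8%. The 6 contrasts were old against young in females, in males and averaged over the sexes, the difference of these age effects (male minus female), and male against female in young and in old. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Levels are given as TMM-normalised CPM, mean ± SD over the 3 libraries of a group. Log2 fold changes are given with an approximate standard error (SE) after the ±. The fit does not report this SE. It was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and is unreliable where counts are near 0. Adjusted p-values of genes are those of the edgeR test unless another tool is named.

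For gene groups, 38 lists were fixed in advance, including markers of the other intestinal cell types that the gate could hold. The 35 lists with at least 3 tested genes were tested with limma's camera (limma 3.58.1), two-sided, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Adjusted p-values of lists are Benjamini-Hochberg values over these lists. Counts of called members refer to the adjustment over all tested genes, and a second count was adjusted over the list alone. The genes named were also fixed by rule: in each age comparison the 8 largest increases and 8 largest decreases among called genes with a mean of at least 2 log2 CPM and no overlap between old and young libraries (within each sex for the average), in the sex comparisons the 6 largest each way, 15 fixed genes, and up to 4 members of a list with the smallest p-values. Most genes with predicted names and small RNAs were counted and not named, apart from genes said to be chosen after their values were seen. The rule still named a clone-named gene in males. In the comparison of old males with old females it named a clone-named gene annotated among small and structural RNAs.

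The procedure was tested on simulated counts drawn from the means and library sizes of these samples, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from the more abundant ones, and counts were drawn without correlation between genes or outlying libraries. Recovery in the real data may thus be lower. The averaged comparison recovered 80% of the 2-fold and 95% of the 4-fold changes among 14577 simulated genes. In females 45% and 95%, and in males 42% and 84%, were recovered. The difference of the age effects recovered 10% of the 2-fold and 75% of the 4-fold changes. The sex comparison recovered 42% and 90% in young and 43% and 92% in old. Genes called without a simulated change numbered 11 in females, 3 in males, 9 for the average, 2 for the difference, 10 for sex in young and 7 for sex in old.

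Other settings chosen before the data were examined were DESeq2-style size factors in edgeR, no filter on low counts, a stricter filter (1 CPM in 6 libraries), DESeq2 1.42.0, a replicate block over all groups and within each sex, 1 surrogate variable (sva 3.50.0), leaving out mitochondrial and structural RNAs, fitting only the 6 libraries compared, and leaving out each library in turn. After the data had been seen, 4 more were added, namely a term for library type (pseudogene share of counts above or below 2.5%), the log2 share of long non-coding RNA as a covariate, protein-coding genes with 1 locus only, and leaving out female old replicate 1 and male young replicate 3 together. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.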

Results

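Total RNA was sequenced from Lgr5-positive intestinal stem cells of young and old mice of both sexes, with 3 libraries in each of the 4 groups. The series concerns the transcriptome of the mouse intestine during aging. Female libraries held 7634936 to 12292612 counts in named genes. Male libraries held 18696045 to 33350636, except male young replicate 3, which held 9683799.

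Stem cell markers were detected in the gated population of every group. Lgr5, a receptor for R-spondins and the gene whose knock-in reporter the sort is based on (chromosome 10, 114887367 to 115024836, build mm9), had 128 ± 18.2 CPM in young and 149 ± 22.6 CPM in old females, and 177 ± 25.8 CPM in young and 220.4 ± 30.8 CPM in old males. Olfm4, a secreted stem cell marker, had 15010 ± 1616 CPM in young females, 14160 ± 3656 CPM in old females, 21060 ± 9700 CPM in young males and 13600 ± 388 CPM in old males. Averaged over the sexes, none of the 30 stem cell markers, among them Ascl2 (0.14 ± 0.20) and Smoc2 (0.03 ± 0.14), was called with age, and the median log2 fold change of the list was 0.01 (edgeR quasi-likelihood test). The 34 cell cycle genes likewise held no called member, and Mki67, a marker of dividing cells, had a log2 fold change of 0.01 ± 0.19. The smallest adjusted p among stem cell markers was that of Tnfrsf19, at 0.0611, with a log2 fold change of -0.50 ± 0.13. Markers of T cells, myeloid, stromal and endothelial cells were mostly below the filter, with 5 of 20, 5 of 18, 3 of 17 and 5 of 12 listed genes tested.

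**Figure D1:**
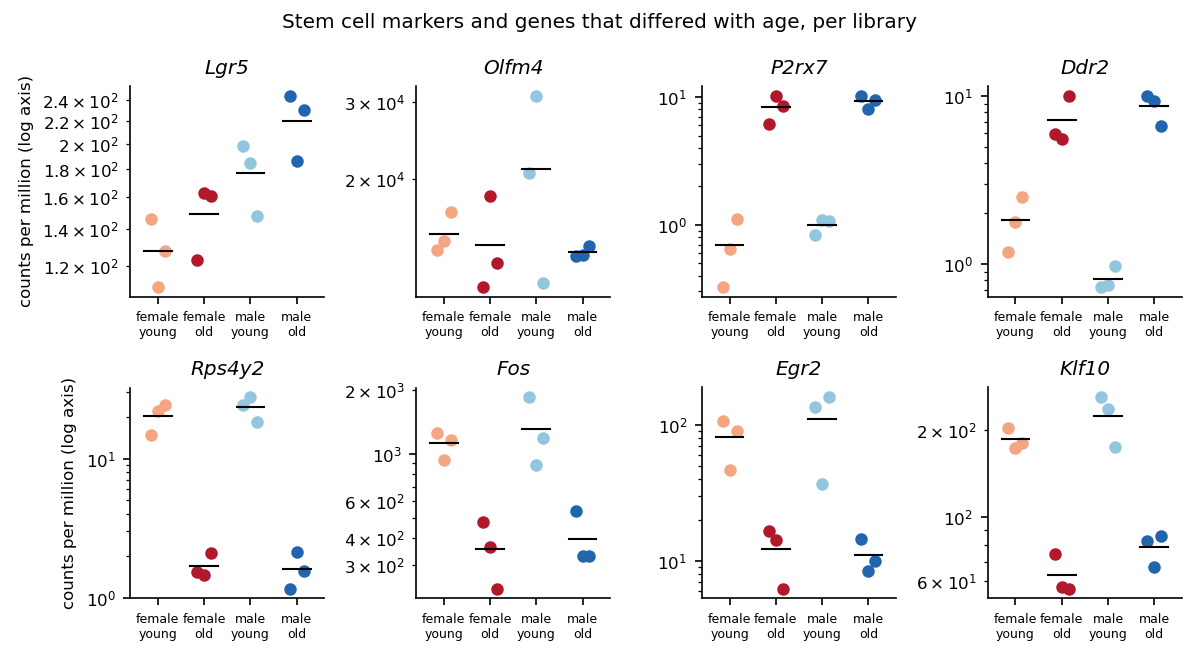
CPM (log axis) of 8 genes in each of the 12 libraries, with the group mean as a bar. Lgr5 and Olfm4 overlapped between ages, while P2rx7 and Ddr2 lay higher and Rps4y2, Fos, Egr2 and Klf10 lower in all old libraries than in all young libraries of the same sex.

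Libraries differed in composition along lines other than age. Annotated pseudogenes held 2.90% to 3.44% of the counts in the 6 female libraries and 2.96% in male young replicate 3, against 2.08% to 2.28% in the other 5 male libraries. Long non-coding and other unclassified transcripts held 1.36 ± 0.12% of the counts in young females, 1.06 ± 0.26% in old females, 0.845 ± 0.423% in young males and 0.754 ± 0.014% in old males (SD, n = 3). Male young replicate 3 also had 3193 CPM of Lyz1, the Paneth cell lysozyme, against 462.9 and 532.4 CPM in the other young males. Female old replicate 1 stood apart on the second principal component and had 128 CPM of Alpi, an enterocyte alkaline phosphatase, against 16.5 and 10.4 CPM in the other old females. Male old replicate 1 had 63.9 CPM of Cd74, the MHC class II invariant chain, against 1284 and 828 CPM in the other old males.

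**Figure D2:**
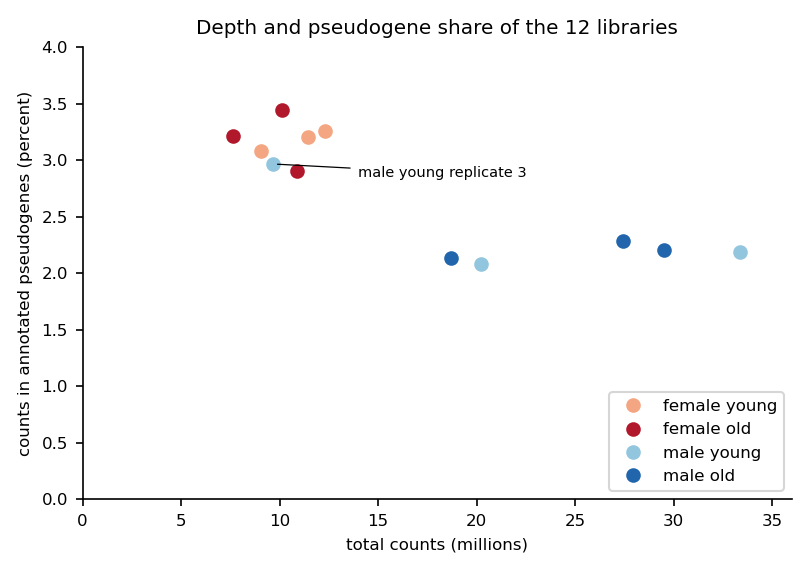
Share of counts in annotated pseudogenes (percent) against total counts for each of the 12 libraries. Male young replicate 3, at 9683799 counts and 2.96%, lies with the female libraries, and the other 5 male libraries lie at 2.08% to 2.28%.

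Averaged over the sexes, the old libraries of sorted cells held more transcripts of P2rx7, Ddr2 and Anks6, among others, and fewer of Rps4y2, Egr2 and Areg. P2rx7, an ATP-gated ion channel (chromosome 5, 123093920 to 123141441), was 10.5-fold higher, from 0.693 ± 0.396 CPM to 8.35 ± 2.05 CPM in females and from 0.992 ± 0.145 CPM to 9.30 ± 1.10 CPM in males (adjusted p = 3.37e-05). Ddr2, a collagen receptor tyrosine kinase (chromosome 1, 171902439 to 172040632), was 6.49-fold higher (adjusted p = 0.000177). The other large increases were those of H2-Eb1 (6.71-fold), an MHC class II beta chain, Anks6 (5.79-fold), Odz4 (5.03-fold), Ly6e (4.87-fold), an interferon-inducible surface protein, Vmn1r90 (4.48-fold), listed as a vomeronasal receptor, and Guca2b (4.23-fold), the gut peptide uroguanylin. Rps4y2, a ribosomal protein S4 gene (chromosome 6, 148303178 to 148304120), was 13.2-fold lower, from 20.4 ± 5.06 CPM to 1.69 ± 0.348 CPM in females and from 23.4 ± 4.64 CPM to 1.61 ± 0.480 CPM in males (adjusted p = 1.03e-06), and may share reads with its close paralog.

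The other large decreases included transcription factors, cytokines and a chaperone. Egr2, an immediate-early transcription factor, was 8.08-fold lower, Areg, the EGF receptor ligand amphiregulin, 7.98-fold, Ccl20, a chemokine, 7.29-fold, Atf3, a stress-induced transcription factor, 7.06-fold, Tnf 6.25-fold, Cyr61, a matrix protein induced by YAP, 6.17-fold, and Hspa1b, an inducible heat shock protein, 5.57-fold. Of 24 tested immediate-early and dissociation-response genes, 18 were lower, none was higher and 6 were not called, and 20 were lower when adjusted over the list alone. Fos fell from 1118 ± 164 CPM to 356 ± 122 CPM in females and from 1306 ± 493 CPM to 397 ± 119 CPM in males (log2 fold change -1.69 ± 0.22, adjusted p = 0.00176), and Egr1 (-1.46 ± 0.19), Nr4a1 (-2.16 ± 0.27) and Ier2 (-1.21 ± 0.17) were lower with it. The list had a median log2 fold change of -1.30 (camera adjusted p = 5.53e-27, and adjusted p = 0.245 with an estimated correlation). When 1 library was left out, 13 to 18 of its members were called, with 13 without female old replicate 2 or any male old replicate.

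Of 12 tested NF-kB targets 6 were lower and 6 not called (9 lower when adjusted over the list alone), with Nfkbia, the inhibitor that NF-kB induces, at -1.17 ± 0.18 and Nfkb2 at -1.19 ± 0.23 (camera adjusted p = 1.77e-09, and adjusted p = 0.245 with an estimated correlation). Cxcl1, a chemokine gene of this list, had 4.76 ± 2.83 CPM in young and 0.120 ± 0.134 CPM in old females. The old value lies below the floor of 3 counts in those libraries (0.276 to 0.393 CPM), so the size of this drop is uncertain. Of 16 heat shock genes 4 were lower, with Dnajb1 at -1.36 ± 0.18 and Dnaja1 at -0.74 ± 0.14 (also 4 when adjusted over the list alone, camera adjusted p = 0.000228, and adjusted p = 0.342 with an estimated correlation). Of 22 unfolded protein and integrated stress response genes 3 were lower (3 lower and 1 higher when adjusted over the list alone), and all 3, Atf4 (-0.99 ± 0.13), Ppp1r15a (-1.83 ± 0.35) and Ddit3 (-1.35 ± 0.30), belong to the integrated stress response. That list did not pass as a whole (camera adjusted p = 0.513). Of 12 fetal-like and regeneration genes 3 were lower, among them Cyr61 and Areg, and Ly6e was higher (camera adjusted p = 0.00788, and adjusted p = 0.245 with an estimated correlation). NF-kB calls were 3 without male old replicate 3, heat shock calls 2 without female old replicate 2 or female young replicates 2 or 3, and calls of the stress response list 1 without female old replicate 2, female young replicate 1 or any male old library.

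Among markers of differentiated cell types, some Paneth, goblet and tuft cell markers were higher in old libraries averaged over the sexes, and edgeR called no enterocyte or enteroendocrine marker. DESeq2 called 11 Paneth, 10 goblet, 6 tuft, 15 enterocyte and 0 enteroendocrine markers, all higher. Of 20 tested Paneth cell markers, which belong to the antimicrobial cells beside the stem cells, 6 were higher and 14 not called (15 higher when adjusted over the list alone), among them the defensin gene Defa-rs1 (2.49 ± 0.33), Defa21 (2.71 ± 0.43), Habp2 (1.59 ± 0.33) and Ang4 (1.87 ± 0.37). The list had a median of 1.60 (camera adjusted p = 4.19e-20, and adjusted p = 0.245 with an estimated correlation). Of 20 goblet cell markers 4 were higher and 16 not called (13 higher when adjusted over the list alone), namely Galnt12 (1.01 ± 0.12), Guca2a (1.60 ± 0.25), Ccl6 (1.66 ± 0.33) and Atoh1 (0.98 ± 0.23), the transcription factor of the secretory lineage (camera adjusted p = 1.47e-13, and adjusted p = 0.245 with an estimated correlation). None of 25 enterocyte markers was called, 19 were higher when adjusted over the list alone, and their median was 2.08 (camera adjusted p = 8.2e-11, and adjusted p = 0.386 with an estimated correlation). Without female old replicate 1 that median was 1.00 and 2 were called, and Alpi had 5.41 ± 3.16 CPM in young and 51.7 ± 66.3 CPM in old females. Of 18 tuft cell markers Rgs13 was higher (1.95 ± 0.36, 8 higher when adjusted over the list alone, camera adjusted p = 1.55e-07, and adjusted p = 0.384 with an estimated correlation). None of 20 enteroendocrine markers was called (0 when adjusted over the list alone, camera adjusted p = 0.000142, and adjusted p = 0.493 with an estimated correlation). Without male young replicate 3, 17 Paneth, 9 goblet and 3 enteroendocrine markers were called and no tuft marker, and without both male young replicate 3 and female old replicate 1 the counts of Paneth, goblet and tuft markers were 18, 11 and 0. No tuft marker was called without male young replicate 2 either, and 1 enterocyte marker was without female old replicate 3. Paneth calls were 3 without female old replicate 2, female young replicate 1 or male old replicate 3. They were 2 without female young replicates 2 or 3 or male old replicate 2. Goblet calls were 7 without female old replicate 1. They were 2 without female young replicates 1 or 3 or male old replicates 2 or 3.

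**Figure D3:**
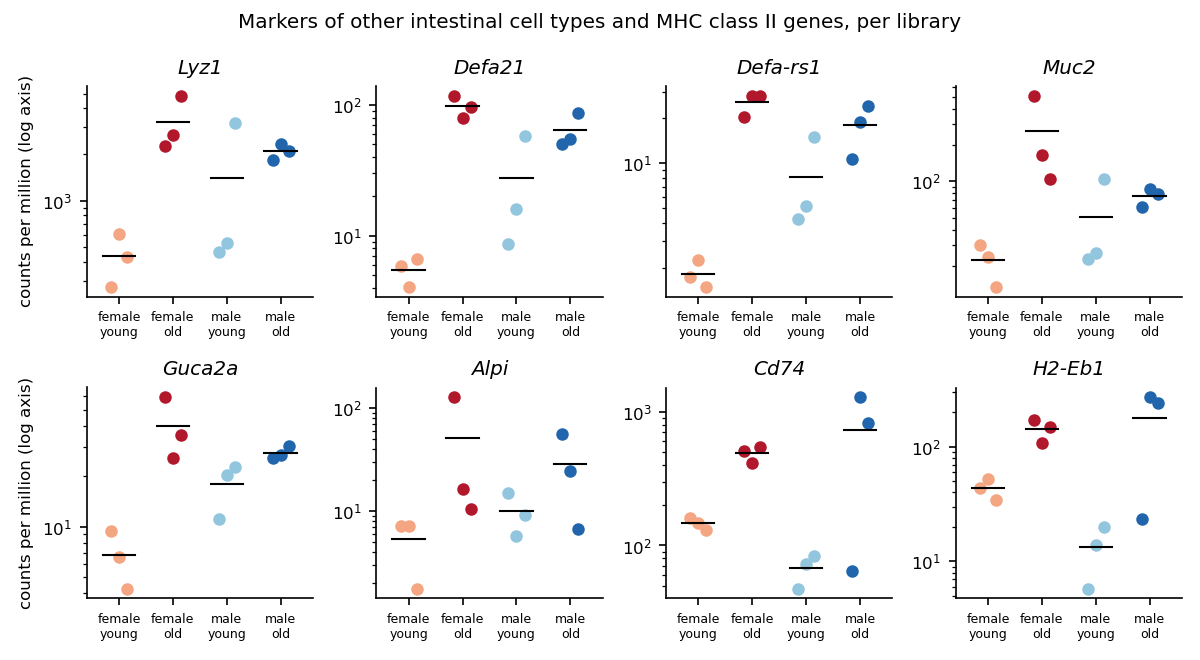
CPM (log axis) of 8 marker genes in each of the 12 libraries, with the group mean as a bar. Lyz1 reached 3193 in male young replicate 3 against 462.9 and 532.4 in the other young males, and Cd74 lay at 63.9 in male old replicate 1 against 1284 and 828 in the other old males.

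Of 8 tested MHC class II antigen presentation genes 4 were higher and 4 not called (7 higher when adjusted over the list alone). These were H2-Aa (3.86 ± 0.79), H2-Eb1 (2.75 ± 0.56), H2-DMb1 (2.35 ± 0.51) and H2-DMa (1.73 ± 0.38), and Cd74 had a log2 fold change of 2.58 ± 0.56 (adjusted p = 0.0531). The list passed as a whole (camera adjusted p = 1.92e-08, and adjusted p = 0.263 with an estimated correlation). When 1 library was left out, 7 members were called without male old replicate 1, the library with little Cd74, and none in any of the other 11 fits. H2-Eb1 was called in 1 of the 12 fits that left out a library. DESeq2 called 7 members of this list. Ptprc, a pan-leukocyte marker of the T cell list that was not called, had 1.15 ± 0.777 CPM in young and 3.81 ± 2.97 CPM in old females, and 1.23 ± 0.762 CPM in young and 3.32 ± 2.54 CPM in old males (log2 fold change 1.61 ± 0.55, adjusted p = 0.144).

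Among the other lists that passed the test with the preset correlation, 1 of 55 replication-dependent histone genes was higher, Hist1h4n at 1.20 ± 0.24 (3 when adjusted over the list alone, camera adjusted p = 8.2e-11, and adjusted p = 0.529 with an estimated correlation). MHC class I genes (22 tested, camera adjusted p = 4.05e-05), PPAR targets and fatty acid oxidation genes (24 tested, 0.000123), type I interferon response genes (27 tested, 0.00358), cholesterol synthesis genes (21 tested, 0.00613) and nuclear oxidative phosphorylation genes (42 tested, 0.0451) had no called member and passed towards higher values. With an estimated correlation their adjusted p-values were 0.416, 0.493, 0.552, 0.664 and 0.769. Cholesterol synthesis genes did not pass without female old replicate 1, male old replicate 2 or male young replicate 2 (adjusted p up to 0.078), nor nuclear oxidative phosphorylation genes without female old replicate 3, female young replicate 1, male old replicate 2 or male young replicate 3 (adjusted p up to 0.484). Adjusted over the list alone, 3 MHC class I, 5 type I interferon and 1 cholesterol synthesis genes were higher. In lists that did not pass, Pmaip1 (-1.77 ± 0.31) and Plaur (-2.50 ± 0.53) were lower among 20 p53 and senescence genes (5 when adjusted over the list alone), Rpl10 (-0.96 ± 0.13) among 75 ribosomal protein genes and Cbx8 (-0.85 ± 0.21) among 24 DNA methylation and Polycomb genes. Lyz2 (1.98 ± 0.41) was higher among 5 myeloid markers. Cdkn1a, a cell cycle inhibitor of the p53 and senescence list, had a log2 fold change of 0.13 ± 0.45, and Stat1, an interferon signalling factor, 0.30 ± 0.14. Wnt targets (20 tested), interferon-gamma response (21), inducible antimicrobial (7), mitochondrially encoded (7), circadian clock (16) and T cell (5) genes had no called member and did not pass. The same held for B cell (3), stromal (3), endothelial (5), Y-linked (4) and X-inactivation and X-escape (6) genes. Among the 13 genes of the Notch list edgeR called Atoh1 (3 higher when adjusted over the list alone). Adjusted over the list alone, 2 T cell markers were higher, 1 clock gene was lower, 1 interferon-gamma response gene was higher and 1 lower, and of the myeloid markers 1 was higher and 1 lower. Of lists too small for the test, both tested exocrine pancreas genes, Cela1 (1.59 ± 0.18) and Clps (2.00 ± 0.41), were higher, and Alas2, the 1 tested erythroid gene, and the 2 tested structural RNAs, Malat1 and Neat1, were not called. When 1 library was left out, the calls ran from 0 to 5 for histone genes, 0 to 3 for p53 and senescence genes, 0 to 4 for MHC class I genes, 0 to 1 for DNA methylation and Polycomb genes, 0 to 2 for myeloid and Notch genes and 1 to 2 for exocrine pancreas genes. Clps was also in the Paneth list, and Atoh1 in both the goblet and the Notch lists.

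In total 362 of 14969 genes were called with age averaged over the sexes, 126 higher and 236 lower, and 360 of them had the same sign in both sexes. Selection on the average of both sexes favours equal signs, so this is no replication between the sexes. Of the 362, 293 were called in neither sex alone. The count of 362 fell to 187 without female old replicate 2, to 193, 184 and 174 without female young replicates 1, 2 and 3, and to 228, 146 and 172 without male old replicates 1, 2 and 3. Of the 16 largest changes, 12 were called in all 12 fits that left out a library, and Ccl20, Tnf, Hspa1b and H2-Eb1 were not. With a term for library type 448 genes were called, 312 of them shared. Male young replicate 3 alone sets that term, and without this library 428 were called.

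**Figure D4:**
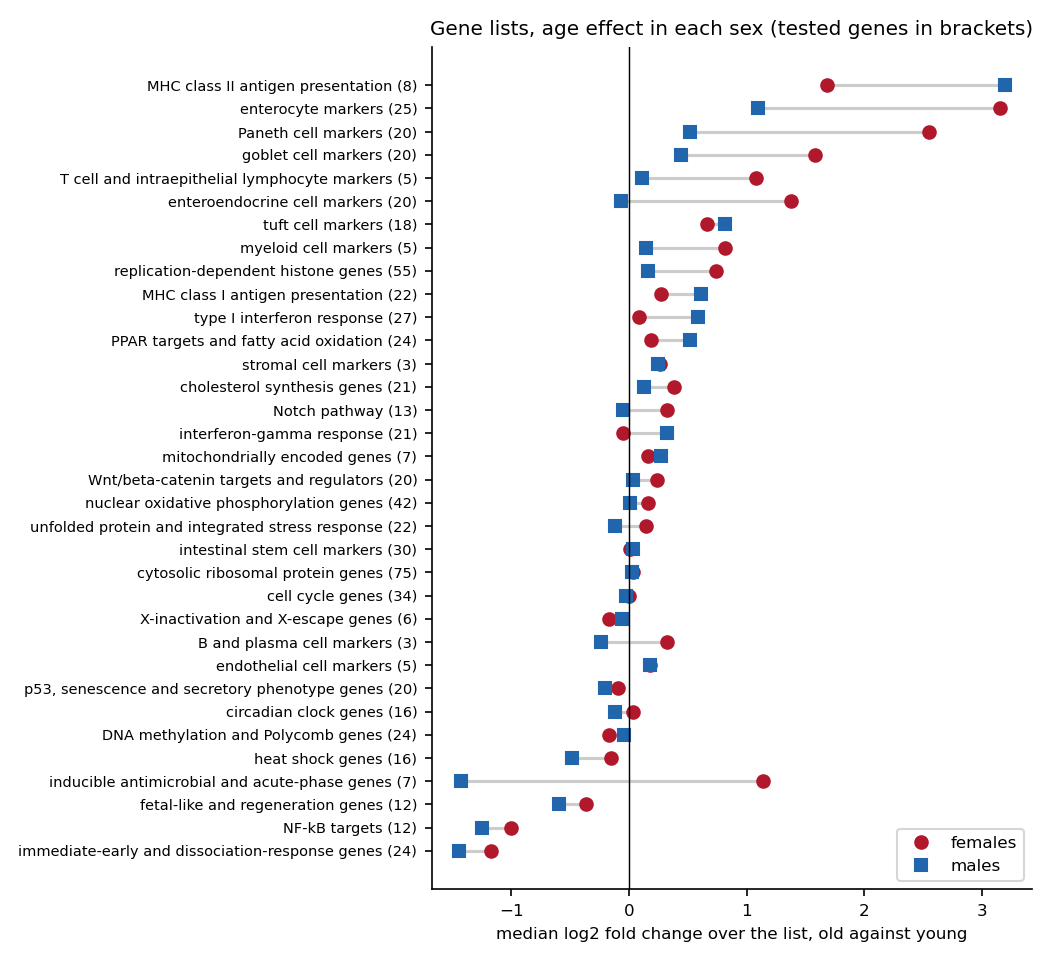
Median log2 fold change of old against young over each gene list with at least 3 tested genes (Y-linked genes left out), for females (circles) and males (squares). Immediate-early genes lay at -1.18 in females and -1.44 in males, and Paneth markers at 2.55 and 0.52.

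In females, the old libraries held more transcripts of P2rx7, among others, and fewer of Rps4y2 and Klf10. Defa21, an alpha-defensin made by Paneth cells (chromosome 8, 22165224 to 22166195), rose 18.0-fold from 5.47 ± 1.31 CPM to 98.1 ± 19.2 CPM (adjusted p = 0.0389). Defa-rs1, a related defensin, was higher by a log2 fold change of 3.81 ± 0.50, P2rx7 was higher 11.8-fold, Ccl6 6.50-fold, Habp2 5.99-fold, Guca2a, the gut peptide guanylin, 5.98-fold, Odz4 5.64-fold and Gp1bb 4.87-fold. On the lower side stood Rps4y2 (12.0-fold), Ier3 (4.97-fold), Ccnl1 (3.17-fold), Klf10 (2.96-fold), a factor induced by TGF-beta (chromosome 15, 38221219 to 38230464), Errfi1 (2.79-fold), a feedback inhibitor of the EGF receptor, Rpl10 (2.68-fold), Id2 (2.67-fold) and Slc20a1 (2.56-fold). Klf10 fell from 186 ± 15.5 CPM to 62.7 ± 10.3 CPM (adjusted p = 0.00227).

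Of the 20 Paneth markers 3 were higher in old females (17 when adjusted over the list alone), and the list had a median of 2.55 (camera adjusted p = 9.31e-25, and adjusted p = 0.349 with an estimated correlation). Lyz1 had 436 ± 169 CPM in young and 3269 ± 1381 CPM in old females (adjusted p = 0.125), and Muc2, the main goblet cell mucin, 22.3 ± 8.37 CPM and 261 ± 220.2 CPM (adjusted p = 0.106). Of the goblet markers 3 were higher, with a median of 1.58 (16 when adjusted over the list alone, camera adjusted p = 1.21e-16, and adjusted p = 0.326 with an estimated correlation). None of the 25 enterocyte markers was called by edgeR (19 higher when adjusted over the list alone), 14 were by DESeq2, and their median of 3.15 was 0.92 without female old replicate 1. DESeq2 called 13 Paneth and 11 goblet markers. The enteroendocrine marker Chga had a log2 fold change of 1.33 ± 0.73 and the tuft marker Dclk1 0.70 ± 0.33. Of the 24 immediate-early genes edgeR called Ier3 lower in females and DESeq2 called 15, with 18 lower when adjusted over the list alone, a median of -1.18 and a log2 fold change of -1.65 ± 0.31 for Fos (camera adjusted p = 1.03e-17, and adjusted p = 0.381 with an estimated correlation). Ier3 was not called in 8 of the 12 fits that left out a library (adjusted p up to 0.18). The count of immediate-early genes was 0 without female old replicates 2 or 3, any young female library or male old replicates 2 or 3. It was 4, 2, 3, 8 and 9 without female old replicate 1, male old replicate 1 and male young replicates 1, 2 and 3. In these fits 0 Paneth markers were called without a young female library, whichever it was, and 1 without female old replicates 2 or 3 or male old replicates 2 or 3. The count was 5 without male young replicates 1 or 2 and 17 without male young replicate 3. Goblet markers numbered 0 without female young replicates 2 or 3, 1 without female young replicate 1 or female old replicate 2 and 9 without male young replicate 3. MHC class II genes had a median of 1.69 with none of 8 called by edgeR or DESeq2, and 5 were called without male old replicate 1 and none without any other library (camera adjusted p = 0.000379, and adjusted p = 0.494 with an estimated correlation).

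The test called 40 genes in females, 25 higher and 15 lower, and 2221 at an unadjusted p under 0.05. The count was 321 without male young replicate 3, where 17 Paneth, 9 goblet and 9 immediate-early genes were called (0 of each without female young replicates 2 or 3), and 499 without that library and female old replicate 1. It was 61 without female old replicate 1, 12 without female old replicate 2, 10, 3 and 4 without female young replicates 1, 2 and 3, 22 and 22 without male old replicates 2 and 3, and 71 and 88 without male young replicates 1 and 2. All 6 female libraries had the higher pseudogene share. With a term for library type, which here acts much as leaving out male young replicate 3 does, 329 genes were called. The female contrast compares female libraries only, all of the same library type. Male libraries and that term thus reach its calls through the dispersion, filter and normalisation shared over the libraries. Fitting only the 6 female libraries gave 294. P2rx7, Rps4y2 and Klf10 were the 3 of the 16 named genes called in all 12 fits that left out a library.

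In males, the old libraries held more transcripts of Ddr2 and P2rx7, among others, and fewer of Rps4y2. Ddr2 rose 10.7-fold from 0.818 ± 0.134 CPM to 8.70 ± 1.79 CPM (adjusted p = 0.00152) and P2rx7 9.34-fold (adjusted p = 0.00154). Vmn1r90 was 5.53-fold higher, Pvt1, a long non-coding RNA beside Myc, 4.24-fold, RP23-43M12.1 3.52-fold, Fam105a 3.15-fold, Cela1, an elastase, 3.03-fold and Ddo, a D-aspartate oxidase, 2.68-fold. RP23-43M12.1 lies within the Lgr5 locus (chromosome 10, 115007042 to 115019504), so its reads cannot be told apart from those of Lgr5 where they overlap. Rps4y2 was 14.6-fold lower (adjusted p = 4.75e-05), Egr2 9.96-fold, Arc 6.84-fold, Arl4d 5.66-fold, Trim35 5.04-fold, Dusp5, a phosphatase that ends ERK signalling, 4.93-fold, Nr4a1 4.66-fold and Trip6 4.32-fold.

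Of the 24 immediate-early genes 7 were lower in old males (20 when adjusted over the list alone), among them Fos (-1.72 ± 0.31), Jun (-1.26 ± 0.23), Egr1 (-1.59 ± 0.27) and Ier2 (-1.42 ± 0.24), and the list had a median of -1.44 (camera adjusted p = 6.71e-34, and adjusted p = 0.172 with an estimated correlation). Dnajb1 (-1.80 ± 0.25) and Dnaja1 (-1.02 ± 0.20) were the 2 called heat shock genes (camera adjusted p = 8.59e-08, and adjusted p = 0.172 with an estimated correlation). MHC class II genes had a median of 3.19 with none of 8 called by edgeR, 7 called by DESeq2 and 7 higher when adjusted over the list alone (camera adjusted p = 5.27e-11, and adjusted p = 0.172 with an estimated correlation), and 7 were called without male old replicate 1 and none without any other library. H2-Ab1 had 19.5 ± 5.64 CPM in young and 202 ± 171 CPM in old males. None of the Paneth markers was called by edgeR or DESeq2, with a median of 0.52, and without male young replicate 3 the median was 1.90 and 4 were called (13 without that library and female old replicate 1). Galnt12 was the 1 called goblet marker, at 0.89 ± 0.17 (adjusted p = 0.0466), but no goblet marker was called in 9 of the 12 fits that left out a library. The other 3 were those without female old replicate 1 or male young replicates 2 or 3. Heat shock calls were 4 without male old replicate 1, 0 without male old replicate 3 and 1 without male old replicate 2, any young female library or any young male library. The immediate-early count ran from 0 without male old replicates 2 or 3 or male young replicate 1 to 12 without female old replicate 3 or male young replicate 2.

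The test called 49 genes in males, 19 higher and 30 lower, and 1198 at an unadjusted p under 0.05. Within the 5 male libraries of lower pseudogene share, that is without male young replicate 3, 40 genes and 1 immediate-early gene were called. A term for library type marks only that library among the males, so it amounts to nearly the same fit. It also gave 40 and 1, which is no second check. The median of the immediate-early list was -1.47 in both of these fits, against -1.44 with all libraries, and DESeq2 called 18 of its 24 members. The count was 77, 28, 32, 27 and 32 without female old replicates 1 and 2 and female young replicates 1, 2 and 3, 18 and 12 without male old replicates 2 and 3, and 29 and 85 without male young replicates 1 and 2. Immediate-early calls were 0 without male old replicates 2 or 3 or male young replicate 1, and 2 without female old replicate 2 or female young replicates 2 or 3. They were 3 without female young replicate 1 or male old replicate 1, and 12 without female old replicate 3 or male young replicate 2. Of the 16 named genes 4, Ddr2, P2rx7, RP23-43M12.1 and Rps4y2, were called in all 12 of these fits.

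The age effects of the sexes were compared directly. Genes called in both sexes are named here after their values were seen. Among them 10 were higher in both, including P2rx7, Ddr2, Cela1, Galnt12, Nfix, Oit1, Tmed6 and Tst, where 0.0317 would be shared by chance (Fisher's exact test, p = 1.93e-24). The 7 genes lower in both included Rps4y2, Klf10, Errfi1, Atf4, Sfn and Spry1, where 0.0301 would be shared by chance (Fisher's exact test, p = 3.88e-16). Fisher's test takes genes, and the female and male calls, as independent. These calls came from the same fit with dispersions shared over all libraries, so the p-values may be too small. Over the 14969 genes, which are not independent, the log2 fold changes of the sexes correlated with Pearson's r of 0.449 and Spearman's rho of 0.408. In the test of the difference 1 gene was called, the long intergenic RNA 1700023H06Rik (chromosome 13, 81023485 to 81024785), a predicted gene named here after its values were seen. It went from 12.1 ± 2.41 CPM to 3.98 ± 0.406 CPM in females and from 2.31 ± 0.453 CPM to 5.85 ± 1.12 CPM in males, a difference of 2.94 ± 0.39 between the male and the female log2 fold change (adjusted p = 0.0421). Of the 12 fits that left out a library, it was called in 1, without male young replicate 3.

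As lists, Paneth markers had a lower age effect in males than in females (median difference -2.16, camera adjusted p = 3.59e-16, and adjusted p = 0.435 with an estimated correlation), as had goblet markers (-1.36, adjusted p = 3.08e-10, and adjusted p = 0.435 with an estimated correlation). Without male young replicate 3 these medians were -0.85 and -0.70. The mean log2 CPM of Paneth markers was 6.31 in that library against 3.64 and 3.86 in the other young males, and without it the median age effect was 1.90 in males and 2.56 in females. MHC class II genes had a higher age effect in males (1.49, adjusted p = 0.0337, and adjusted p = 0.666 with an estimated correlation). They did not pass without female old replicate 2, female young replicates 1 or 2, male old replicates 2 or 3, or male young replicates 1 or 3, each left out alone (adjusted p up to 0.454). In all 15 of 35 lists passed with the preset correlation and none with an estimated one. At an unadjusted p under 0.05 the test of the difference held 567 genes. DESeq2 called 4 genes. No gene was called by edgeR in 11 of the 12 fits that left out a library, and 6 were without male young replicate 3, while 81 were called without that library and female old replicate 1.

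Between young males and females, the sex chromosomes held most of the called genes. Ddx3y (chromosome Y, 597158 to 623056), Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, had no counts in any young female library, whose floor of 3 counts was 0.244 to 0.331 CPM, and 83.7 ± 33.5 CPM, 75.8 ± 23.5 CPM, 68.3 ± 11.9 CPM and 93.1 ± 13.3 CPM in young males. Xist, the RNA that silences one X chromosome (chromosome X, 100655714 to 100678556), had 1502 ± 225 CPM in young females and 2.39 ± 0.546 CPM in young males, so all libraries of these groups matched their labelled sex. Gas7, an actin-binding protein gene, was 3.19-fold higher in males (adjusted p = 0.0469) but was not called in 9 of the 12 fits that left out a library (adjusted p up to 0.384), and 1700023H06Rik, a predicted gene named after its values were seen, was 5.20-fold lower. No other gene was called by edgeR, which gave 7 genes (521 by DESeq2), 5 higher and 2 lower in males, against 2777 at an unadjusted p under 0.05. Of the lists, Y-linked genes (4 of 4 called) and X-inactivation and X-escape genes (1 of 6 called, Xist) passed with an estimated correlation (camera adjusted p = 0.00127 and adjusted p = 0.0112). The latter list had a mean of -1.94 and a median of -0.60, with Xist at -9.33. With the preset correlation alone 9 more lists passed. Among these, Paneth markers lay higher in young males with a median of 1.36 (adjusted p = 7.59e-05, and adjusted p = 0.994 with an estimated correlation) and MHC class II genes lower with a median of -1.35 (adjusted p = 0.0085, and adjusted p = 0.994 with an estimated correlation). Without male young replicate 3 the Paneth median was 0.13 and neither list passed (adjusted p = 0.75 for Paneth and 0.0926 for MHC class II genes). Gas7 was called without female old replicate 1, male old replicate 3 or male young replicate 3 and not without any other library. Among protein-coding genes with 1 locus 4 were called. Without male young replicate 3 the count was 2686, and with a term for library type it was 20. Female and male young libraries of the same library type could be compared only through that single library.

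Between old males and females, pseudogenes were called along with the sex-linked genes. Eif2s3y, Ddx3y, Kdm5d and Uty had 73.7 ± 11.9 CPM, 73.6 ± 6.22 CPM, 74.3 ± 9.44 CPM and 91.8 ± 2.92 CPM in old males and 0, 0, 1 and 2 counts over the 3 old female libraries. Xist had 1451 ± 519 CPM in old females and 4.97 ± 1.54 CPM in old males. Rpl38-ps1, a ribosomal protein pseudogene, had 21.1 ± 4.92 CPM in old males and 0.0757 ± 0.0681 CPM in old females, and AC124613.1, annotated among small and structural RNAs, 16.8 ± 5.85 CPM and 0.307 ± 0.216 CPM. Lower in old males were Rpsa-ps10 (6.16-fold), Rpsa (5.39-fold), which encodes a ribosomal protein, Erh (4.90-fold), Ak7 (4.42-fold), an adenylate kinase, and Uba52 (3.99-fold), a fusion of ubiquitin and a ribosomal protein. Of the 12 named genes, 5 (Eif2s3y, Ddx3y, Kdm5d, Uty and Xist) were called in all 12 fits that left out a library. Rpl38-ps1 was not called in 10 of these fits, AC124613.1, Rpsa-ps10, Rpsa and Uba52 in 9, which include each fit without an old library or a young female library (adjusted p up to 0.196). Ak7 was not called without female old replicate 3 or any male old replicate (up to 0.11), nor Erh without male old replicates 1 or 3 (up to 0.089).

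Of 215 called genes, 47 higher and 168 lower in old males, 136 were pseudogenes (31 higher and 105 lower), which is 63.3% of the called genes against 6.91% of the tested genes. Of 75 ribosomal protein genes 6 were lower and none was higher (19 lower and 3 higher when adjusted over the list alone, camera adjusted p = 2.08e-09, and adjusted p = 0.553 with an estimated correlation). Their calls numbered 3 without female old replicate 1 and 0 without female old replicates 2 or 3 or any male old replicate. They numbered 2, 1 and 1 without female young replicates 1, 2 and 3, and 16, 9 and 21 without male young replicates 1, 2 and 3. Y-linked genes and the list of X-inactivation and X-escape genes again passed with an estimated correlation (camera adjusted p = 0.000855 and adjusted p = 0.0121). Among protein-coding genes with 1 locus 20 were called, and with a term for library type 6. No old male library had the pseudogene share of the female libraries, so sex and library type cannot be told apart in the old groups except through male young replicate 3. The count was 111, 12 and 8 without female old replicates 1, 2 and 3, 120, 29 and 65 without female young replicates 1, 2 and 3, 7, 10 and 7 without male old replicates 1, 2 and 3, and 685 without male young replicate 3.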

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

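Tests of cell carry-over, of a lower stem cell share, of library type and sex, of the long non-coding share and of handling, and the counts over other splits of the libraries, were chosen only after the result was seen, and the test of GC content and length was set beforehand. The groups held 3 libraries each, so no library was tested as far from its group. What follows differed between the sexes under the test of the difference itself, with values given as the male minus the female age effect in log2.

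The long intergenic RNA 1700023H06Rik, at 2.94, was the 1 gene called by edgeR, and DESeq2 called 4. Lists that passed with the preset correlation, none of them with an estimated correlation, were lower in males for inducible antimicrobial genes (median -2.33), Paneth markers (-2.16), enterocyte markers (-1.73), goblet markers (-1.36), enteroendocrine markers (-1.29), histone genes (-0.64), heat shock genes (-0.48), unfolded protein and integrated stress response genes (-0.32) and Notch genes (-0.28). Without female old replicate 1 the median of enterocyte markers was -0.03 (adjusted p = 0.0922) and that of antimicrobial genes -1.33. Without male young replicate 3 the medians were -0.85 for Paneth, -0.70 for goblet and -0.33 for enteroendocrine markers (adjusted p = 0.218 for the last), and the median age effect in males alone went from 0.52 to 1.90 for Paneth and from 0.44 to 0.87 for goblet markers. Lists were higher in males for MHC class II genes (1.49), type I interferon response genes (0.36), interferon-gamma response genes (0.35), PPAR targets (0.35) and MHC class I genes (0.15). Mitochondrially encoded genes passed towards higher values with a mean of 0.23 and a median of -0.0129, and not without female old replicate 1 (adjusted p = 0.369) or male young replicate 3 (0.413). Several lists missed the threshold when a single library was left out. MHC class II genes did so without female old replicate 2, female young replicates 1 or 2, male old replicates 2 or 3, or male young replicates 1 or 3 (adjusted p up to 0.454), and MHC class I genes without female old replicate 2, female young replicate 3, male old replicate 2, or male young replicates 2 or 3 (up to 0.663). Notch genes did so without female old replicates 1 or 2, female young replicate 3, male old replicates 1 or 2, or male young replicate 1 (up to 0.529), and type I interferon genes without female old replicates 2 or 3, male old replicate 2 or male young replicate 2 (up to 0.236). PPAR targets missed it without female old replicate 3, female young replicate 1 or male young replicate 1 (up to 0.18), interferon-gamma genes without male old or young replicate 2 (up to 0.0662), and unfolded protein and integrated stress response genes without male old replicate 3 or male young replicate 1 (up to 0.0685). Of 100 splits of the libraries between ages within each sex, 5 called at least 1 gene. These 5 include the real split, and the other splits were a random draw from those possible. The highest of the other splits called 362 genes, and it is the split that exchanges old and young in males alone. That exchange turns the difference into the averaged age effect, so it is no chance split. The share of splits thus cannot decide, and chance is not excluded for the count of 1 gene.

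All 20 tested Paneth markers had fitted values above 0 in old against young females, of which edgeR called 3 and DESeq2 13, and the list passed with the preset correlation (adjusted p = 9.31e-25) and not with an estimated one (adjusted p = 0.349). edgeR called 17 without male young replicate 3, 5 without male young replicates 1 or 2, 1 without female old replicates 2 or 3 or male old replicates 2 or 3, and 0 without any of the young female libraries, each left out alone. A lower share of stem cells could raise the markers of every other cell type alike. That form is argued against as the whole cause by the Paneth minus tuft marker level. This level differed by 1.92 (log2) between old and young females, and the lowest old library lay 0.70 above the highest young one. The Paneth minus enteroendocrine level parted old from young likewise (1.44, with the lowest old library 0.53 above the highest young one), but the Paneth minus goblet and Paneth minus enterocyte levels overlapped between the ages (0.98 and 0.60). The medians of all 4 of these other lists were above 0 in females. A lower share that raises the lists unequally, or acts together with another change, therefore stays open. The stem cell list had a median of 0.00, which cannot decide, since a small loss of stem cells would barely move it. Paneth cells that pass the gate remain open, although a sort for high Lgr5-eGFP should remove them. All 14 markers with at least 4 log2 CPM were above 0, but this follows from all 20 being above 0 and adds no evidence. Lyz1 reached 3269 ± 1381 CPM in old females. The young library male young replicate 3 also had 20 of 20 markers above the mean of the other young males, but its shifts correlated with the female age effect only at r = 0.116 over these 20 genes, which are not independent, so the test did not decide. A change of these genes within stem cells with age stays open as well, untested, and 2 of the 20 markers, Clps and Wnt3, were also in other lists.

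Of 24 immediate-early genes 18 were lower in old libraries averaged over the sexes (13 without female old replicate 2 or any male old replicate). By edgeR 1 was called in females and 7 in males, against 15 and 18 by DESeq2. When 1 library was left out, the count in females was 0 without female old replicates 2 or 3, any young female library or male old replicates 2 or 3. It was 4, 2, 3, 8 and 9 without female old replicate 1, male old replicate 1 and male young replicates 1, 2 and 3. In males it was 0 without male old replicates 2 or 3 or male young replicate 1, and 1 without male young replicate 3. It was 2 without female old replicate 2 or female young replicates 2 or 3, 3 without female young replicate 1 or male old replicate 1, and 12 without female old replicate 3 or male young replicate 2. The list passed with the preset correlation and not with an estimated one (adjusted p = 0.245 averaged, 0.381 in females and 0.172 in males). Fitted values of 21 members were below 0 in both sexes, called or not. Bias by GC content or length is argued against: the median was -1.30, and the lowest median of 10000 random lists matched on both was -0.23. A different long non-coding share of the libraries is argued against as the whole cause, since with the share as a covariate the median was -1.16 and 18 of 24 members were called. Handling before lysis cannot be told apart from age, because the labels give no order or time of processing, and these genes respond to dissociation, so the lower values may reflect either the animals' age or a different delay or stress before lysis.

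Of the 215 genes called between the sexes in old libraries, 136 were pseudogenes. Library type is a candidate explanation: of the 71 called genes off the X and Y chromosomes that are not pseudogenes, male young replicate 3 differed from the other young males towards the females in 64, or 90.1%. Sex itself cannot be told apart from library type, since with a term for library type 6 genes were called and a single male library carries that term. Pseudogenes, whose share defined the library type, went the same way in 135 of 136 and were not used for this test. The split was by annotated class only, so Rpsa-ps10, annotated as protein-coding, and ribosomal protein genes stayed among the 71. Such genes may share reads with pseudogenes, so this test is not fully independent of how library type was defined.

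With the real ages the averaged age comparison called 362 genes. Of 100 splits of the libraries within the sexes 1 (the real one) gave as many, and the highest of the others called 27. These 100 are the real split and a random draw from the other possible splits. A higher count among the splits not drawn is therefore not excluded. A chance assignment of these libraries is thus argued against for this count at a share of 0.05. The splits take the libraries as exchangeable, and the labels do not say that each came from a separate animal. Chance between animals or preparations is therefore not excluded. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. There the real split called 40 genes in females against a highest other of 0, 49 against 12 in males, 7 against 1 between the sexes in young and 215 against 0 in old, with 1 split as large in each.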

How the results depend on the processing

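The library type term, the long non-coding share, the restriction to protein-coding genes with 1 locus and the joint removal of a pair of libraries were chosen only after the data were seen. The other settings were planned. Counts of called genes are given in the order females, males, averaged, difference, sex in young, sex in old, with 40, 49, 362, 1, 7 and 215 in the main analysis. DESeq2-style size factors, the stricter filter and leaving out structural and mitochondrial RNAs kept every count within 1.5 times. No filter on low counts gave 942, 542, 1473, 247, 1169 and 890, and DESeq2 554, 273, 1015, 4, 521 and 663. One surrogate variable gave 241 in females, 0 for the difference and 6 for sex in old, and only the 6 libraries compared gave 294, 21 and 487 in females, males and sex in old. The library type term gave 329 in females, 6 for the difference, 20 and 6 for sex in young and old. The long non-coding share gave 187, 187 and 770 for females, males and the average. Protein-coding genes with 1 locus gave 0, 4 and 20 for the difference and sex in young and old. Without female old replicate 1 and male young replicate 3 the counts were 499, 184, 81, 3471 and 524 for females, males, the difference and sex in young and old. Leaving out 1 library at a time gave 3 to 321 in females, 12 to 85 in males, 146 to 469 for the average, 0 to 6 for the difference, 6 to 2686 for sex in young and 7 to 685 for sex in old. Unless a setting itself tests fewer genes or libraries, the cause was not tested.

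The replicate numbers did not meet the rule for pairs, which asked for a correlation over 0.1 in every same-numbered pair: same-numbered libraries of different groups had correlations of -0.24 to 0.21 in their deviations from the group means, over 0.1 in 4 of 18 pairs against 5 of 36 pairs with different numbers. Within a sex it was over 0.1 in 3 of 6 same-numbered pairs (median 0.0985) against 1 of 12 others, so a partial pairing within a sex stays open. Of 12 libraries 5 were closest to one of their own number. The replicate block gave 72 in females and 0 for the difference (576 at an unadjusted p under 0.05), and the replicate block within sex 135 in females and 76 in males, and other counts stayed within 1.5 times. For the difference the block within sex called 1 gene, lower where the main one was higher, so 1700023H06Rik was called under neither block.

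Of 118 calls of named genes, none reversed. The call was kept by all 118 with DESeq2 and with no filter, by 116 with DESeq2-style size factors, by 84 with the library type term and by as few as 60 when 1 library was left out. Of 90 list calls, 4 were kept with an estimated correlation and 87 with the replicate block. In the sex comparisons the library type term rests on male young replicate 3, the only male library of the females' type. That library's own levels thereby enter the comparison, so reversals with the term rest on it. Its Paneth markers had a mean log2 CPM of 6.31, against 3.64 and 3.86 in the other young males. Directions of lists reversed as follows, with camera adjusted p-values. With the library type term, in young these were stem cell markers (0.698), NF-kB targets (0.00265), heat shock genes (0.0108) and mitochondrially encoded genes (0.0189), and in old stem cell markers (0.162), Wnt targets (0.594), Paneth (2.75e-12), goblet (0.037) and enteroendocrine markers (0.037), immediate-early genes (0.037) and mitochondrially encoded genes (0.475). Without the pair of libraries, cell cycle genes reversed in females (0.00315), for the difference (0.00016) and for sex in old (0.0379), stem cell markers (0.0225) and mitochondrially encoded genes (0.428) for the difference, and enterocyte markers for sex in old (0.209). With 1 library left out, cell cycle genes reversed without female old replicate 1 in females (0.00117, up to 0.685 over these fits), for the difference (4.01e-05, up to 0.839) and for sex in old (0.012, range 0.000484 to 0.889), as did enterocyte markers for sex in old (0.1, range 2.51e-07 to 0.434). Histone genes reversed in males without male old replicate 2 (0.905, from 0.000174), ribosomal protein genes in males without male young replicate 1 (0.0226, range 0.0012 to 0.824), and MHC class II genes for sex in old without male old replicate 1 (0.000173, up to 0.69). Depth limits genes near the floor of 0.0900 to 0.393 CPM, and the simulated recovery of 2-fold differences between the age effects was 10%.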

Other observations

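Several genes outside the lists separated old from young libraries in both sexes, chosen here after their values were seen. BC064078, a predicted gene, had 9.28 ± 1.44 CPM in young and 27.7 ± 12.8 CPM in old females and 4.81 ± 0.874 CPM in young and 39.2 ± 2.61 CPM in old males (4.92-fold higher, adjusted p = 5e-05). Gas7 was 3.19-fold higher with age averaged over the sexes (adjusted p = 0.000427), from 3.38 ± 0.0692 CPM to 15.7 ± 4.36 CPM in females. Nfix, a nuclear factor I transcription factor, was 1.98-fold higher, Tst, a mitochondrial sulfurtransferase, 2.35-fold, and Oit1 1.77-fold (adjusted p = 0.00116, 0.00105 and 0.00105).

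The inducible antimicrobial genes had a median log2 fold change of 1.14 in females and -1.43 in males, with none of 7 called by edgeR or DESeq2 in either sex. The median was 0.59 in females without female old replicate 1, and in males -0.80 without male young replicate 3 and -0.95 without male old replicate 1. Reg3g, an antibacterial lectin, had 40.2 ± 22.1 CPM in young and 79.1 ± 60.3 CPM in old females, and 85.8 ± 36.9 CPM in young and 23.4 ± 4.74 CPM in old males (difference of the log2 fold changes -2.85 ± 0.90, adjusted p = 1). Reg3b, a related lectin, had 124 ± 125 CPM and 274 ± 281 CPM in young and old females, and 181 ± 129 CPM and 28.0 ± 25.4 CPM in young and old males.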
